A study of Arabidopsis thaliana with 24 samples.

How the data were processed

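The series covers 24 libraries of Arabidopsis thaliana seedlings, per the labels: 8 RNA-seq libraries and 16 chromatin immunoprecipitation (ChIP-seq) libraries against histone H3 or H3 trimethylated at lysine 27 (H3K27me3). Seedlings were diploid (2x) or tetraploid (4x) and belonged to the ecotypes Col-0 or Ler, with 2 RNA-seq libraries for each combination of ecotype and ploidy. The ChIP-seq libraries were not analysed here. Per the labels' protocols, plants were grown in soil at 22 °C under days of 16 h or 8 h of light, and the labels do not say which day length these libraries came from. RNA came from seedlings 2 weeks old, was selected for poly(A), and was made into libraries with a NEBNext Ultra kit, per the labels' protocols. Whether counting used strand is not given in the sources used here.

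The submitters' processing notes name HISAT2, Subread, DESeq2 and the genome build TAIR10, without versions. The deposited data used here are 2 tables of the authors' DESeq2 comparisons, one per ecotype. Per the file headers, each gene has a mean normalized read count, which is a signal averaged by the authors over all 4 libraries of the table. The authors' log2 fold change between ploidies and its standard error follow, on the log2 scale, and are deposited without shrinkage, since the Wald statistic equals their ratio. The deposited Wald statistic is a score with no fixed range. The deposited p-values are the authors' Wald p and its Benjamini-Hochberg adjusted value, which is blank for genes of low mean count. The lowest mean count with an adjusted p was 1.16 in the Col-0 table and 7.23 in the Ler table. Values per library are not in these tables, so no count model was refitted and no replicate could be left out. The test set in advance for tables with per-library counts was therefore replaced by its stated fallback, the authors' adjusted p under 0.05.

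The headers do not state the sign of the fold change. It was read as tetraploid over diploid, so that positive values are higher in the tetraploid. This reading rests on the higher FLC known for tetraploid Col-0 in this study and on the low ESP and high ESM1 known for diploid Col-0, both of which it gives. For Ler it rests on the same naming and procedure. All directions below depend on it.

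The Ler table lists 270 identifiers that join an accession name to a locus code and no organelle genes, while the Col-0 table lists 177 organelle genes. The annotations behind the tables therefore differ, and the tables were normalized separately. Identifiers were matched as written to a gene table of the assembly TAIR10.1, which matched 98.7% of those in Col-0 and 98.5% of those in Ler. That table was used for names and gene order only, since its assembly differs from the authors' build.

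Depth was taken from the tables themselves. The lowest mean counts repeat in 4 steps, each the value of 1 read in 1 library, which gives the 4 size factors of a table. Size factors ran from 0.92 to 1.14 in Col-0 and from 0.92 to 1.08 in Ler, and the mean library total was 22343366 and 22138532 normalized reads. Size factors could be placed by ploidy, through the sign of the fold change, but not by replicate number. Mean counts and reads per ploidy were then implied from the authors' mean and fold change. A gene with under 0.5 implied reads over a ploidy is called without reads there, since such fits came out at 0.37 at most in called Col-0 genes and all others at 0.992 or more. This limit was chosen after seeing the data. The limit first used, 1 read, also took in 12 called Col-0 genes with 1 read, and the tests of explanations gave the same verdicts with it. Its fold is given as a lower bound against a floor of 3 counts over the group, and with 1 to 3 implied reads a 95% exact binomial interval of the ratio is given. Floors and intervals cover counting error only. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

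The difference between ecotypes was tested with a two-sided Wald test of the Ler minus the Col-0 log2 fold change over the root of their summed squared standard errors, with Benjamini-Hochberg adjustment over 21361 shared identifiers. On simulated estimates, the deposited standard errors were taken as exact and differences were placed only in genes with a mean count of at least 100 in both tables. There this test recovered 78% of differences of 1 and 98% of differences of 2 on the log2 scale, and 8.33% of calls over 21361 genes were false. The deposited difference statistics had 1.25 times the spread of the theoretical null, so that share is not the error of the calls below. Overlap was tested with two-sided Fisher's exact tests over 18240 genes with an adjusted p in both tables. The 25 gene lists were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the Wald statistics, with a preset inter-gene correlation of 0.01 and adjustment over the lists. A correlation estimated from the libraries could not be computed without values per library. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

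The lists, the tests and the alternatives were set before the data were examined, except where stated. Genes named are FLC, MAF1 to MAF5, SVP, FT, SOC1, CO, CLF, SWN, EMF2 and LHP1 in all comparisons. To these come the 6 largest rises and 6 largest falls per ecotype among called genes with a mean count of at least 100, and up to 4 called members per list with the smallest adjusted p, or 2 with the smallest p where none was called. For the difference, the 5 largest in each direction are named among called genes with a mean count of at least 100 in either table. For the overlap, the 5 genes per shared direction with the largest smaller change are named, with a mean count of at least 100 in both tables. Other genes are said to have been chosen after their values were seen. Alternatives were stricter thresholds, a minimum fold change, filters on mean count, adjustment without a filter, shrinkage, an empirical null that rescales the Wald statistics, recentring, ranks and a correlation of 0.05 for lists. For single genes, adjustment without a filter, the empirical null and recentring were run, and for single differences the empirical null.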

Results

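RNA from diploid and tetraploid seedlings of the Arabidopsis ecotypes Col-0 and Ler was sequenced in 8 libraries, 2 per ecotype and ploidy. The study asked how genome duplication relates to flowering time and H3K27 trimethylation in these ecotypes, and the transcript side of that question is reported here. The authors' deposited table for Col-0 listed 23202 genes and that for Ler 23059, each with a mean over 4 libraries. Libraries averaged 22343366 normalized reads in Col-0 and 22138532 in Ler, and size factors within a table differed by at most 1.25 times. For genes with a mean count of at least 100, the median standard error of the log2 fold change was 0.15 in Col-0 and 0.16 in Ler. Fold changes are tetraploid over diploid, a direction that the tables do not state and that was inferred, and each ± is the authors' standard error.

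In Col-0, FLC, the MADS-box repressor of flowering, was 6.17-fold higher in tetraploid seedlings in the authors' deposited table (log2 fold change 2.63 ± 0.17, adjusted p = 6.7e-49, mean count 560). From that mean and fold change, its implied count was 156 in diploids and 964 in tetraploids. The direction for FLC was itself a ground for the sign reading, so only its size is a separate result. The authors' deposited table also called SVP, a partner of FLC, lower (−0.53 ± 0.12, adjusted p = 1.8e-04), and MAF5, a relative of FLC, lower at a mean count of 30.7 (−1.88 ± 0.62, adjusted p = 0.02). MAF1, MAF2, MAF3 and MAF4 had log2 fold changes of 0.08 ± 0.13, 0.00 ± 0.15, −0.08 ± 0.19 and 0.33 ± 0.38 in the authors' deposited table, none of them called. The floral integrator SOC1 fell by 0.84 ± 0.27 (adjusted p = 0.014) in the authors' deposited table. FT, the mobile flowering signal, was listed there at a mean count of 7.15 (authors' deposited table, −0.79 ± 1.18, adjusted p = 0.8), too low to show a change of that size. CO, which activates FT, gave −0.58 ± 0.58 (adjusted p = 0.65) in the authors' deposited table.

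Of the 19 floral repressors listed in Col-0, 4 rose and 3 fell, and 7 were called when adjusted over the list alone. Besides FLC and SVP, the authors' deposited table gave TEM2, a repressor of FT, as lower (−1.76 ± 0.25) and SMZ as higher (0.59 ± 0.13). The list as a whole was not shifted (cameraPR adjusted p = 0.61), and its median of −0.04 and the test's upward direction differed in sign. Among 18 floral promoters, 4 fell and 0 rose, and 4 were called when adjusted over the list alone. Besides SOC1, these were AGL24 (−2.45 ± 0.32), SPL4 (−1.94 ± 0.49) and GI (−0.42 ± 0.13) in the authors' deposited table. The promoter list missed the threshold with statistics (adjusted p = 0.073) and passed it with ranks (adjusted p = 0.012). The empirical null ended the calls of MAF5, SOC1 and GI, with adjusted p of 0.18, 0.15 and 0.13, while adjustment without a filter and recentring left them between 0.01 and 0.022.

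Among the listed Polycomb genes in Col-0, 1 was called. LHP1, which binds H3K27me3, rose by 0.69 ± 0.15 (adjusted p = 5.7e-05) in the authors' deposited table and was the called member among 12 listed genes of the Polycomb machinery, 1 also when adjusted over the list alone. The H3K27 methyltransferase genes CLF and SWN gave −0.19 ± 0.16 and 0.06 ± 0.12 and the complex member EMF2 0.06 ± 0.13 in the authors' deposited table, all uncalled. Of 5 H3K27 demethylase genes and 16 listed developmental genes silenced by Polycomb, 0 were called in the authors' DESeq2 results, over all genes and when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Of the 16 silenced genes only 4 had a mean count of at least 10 (median 3.7), so most were too low to show a change of moderate size. The smallest p in these lists belonged to REF6 (0.11 ± 0.13) and JMJ32 (−0.46 ± 0.59) and to STM (−0.45 ± 0.35) and SEP1 (−1.44 ± 1.07) in the authors' deposited table. Among 13 listed activators of FLC, PIE1 rose (0.35 ± 0.12) and FRI fell (−2.52 ± 0.43, mean count 67.7) in the authors' deposited table, and 2 were called when adjusted over the list alone. Whether the listed activators act on FLC in these ecotypes was not tested. Of 10 genes of FLC-repressing pathways, FVE rose (0.28 ± 0.10, adjusted p = 0.039) in the authors' deposited table, and 0 were called when adjusted over the list alone. The empirical null ended the calls of PIE1 and FVE (adjusted p of 0.21 and 0.25, against 0.029 to 0.047 without a filter or with recentring).

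**Figure D1:**
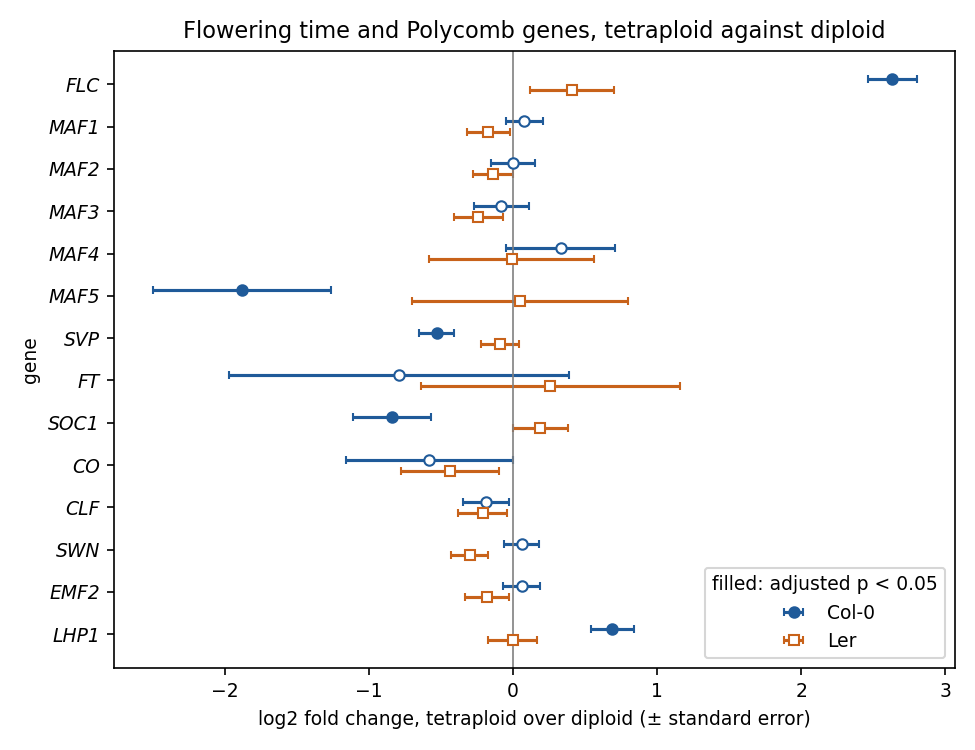
Log2 fold change, tetraploid over diploid, of flowering time and Polycomb genes in Col-0 (circles) and Ler (squares), from the authors' deposited table of each ecotype; bars are the authors' standard errors and filled symbols have an adjusted p under 0.05. FLC stands at 2.63 in Col-0 and 0.41 in Ler, and the filled symbols are FLC, MAF5, SVP, SOC1 and LHP1 in Col-0.

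Over all genes in Col-0, 3290 of 21420 with an adjusted p were called, 1527 higher and 1763 lower in the tetraploid, and 1094 of them changed at least 2-fold. The empirical null left 1799, 787 higher and 1012 lower, and shrinkage with a local false sign rate gave 5126, 2511 higher and 2615 lower. Genes of aliphatic glucosinolate synthesis, the methionine-derived defence compounds of crucifers, rose together. Of 13 members, 11 rose and 0 fell, and 13 were called when adjusted over the list alone, 12 higher and 1 lower (cameraPR adjusted p = 7.4e-45). Examples in the authors' deposited table were CYP79F1 (1.77 ± 0.08), BCAT4 (1.86 ± 0.09) and MAM3 (2.23 ± 0.19). Of 9 indole glucosinolate genes, 4 rose, among them SUR1 (0.58 ± 0.09) and SOT16 (0.59 ± 0.11) in the authors' deposited table, and 5 were called when adjusted over the list alone. That list's adjusted p of 0.047 became 0.12 at a correlation of 0.05, 0.064 with ranks and 0.052 with the count filter.

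Iron deficiency genes were higher in tetraploid Col-0, with 10 of 15 members up, 0 down, and 12 called when adjusted over the list alone (cameraPR adjusted p = 2.7e-06). The authors' deposited table gave the transcription factor gene BHLH38 as 21.4-fold higher (4.42 ± 0.84), and the iron-signalling peptide genes IMA1 and IMA2 at 1.56 ± 0.26 and 1.41 ± 0.20. Of 9 listed heat shock genes, 3 rose, 0 fell, and 3 were called when adjusted over the list alone. These were HSP70 (2.92 ± 0.11), HSFA2 (1.74 ± 0.23) and HSP101 (1.02 ± 0.14) in the authors' deposited table. The heat shock list's cameraPR adjusted p was 1.3e-07 with statistics, where HSP70 weighs heavily, and 0.012 with ranks. Of 19 listed ABA and cold response genes, 6 rose, 2 fell and 9 were called when adjusted over the list alone. P5CS1 rose (1.38 ± 0.09) and KIN2 fell (−1.01 ± 0.10) in the authors' deposited table, and the list's adjusted p of 0.049 became 0.15, 0.064 and 0.053 under its alternatives.

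Lignin, photosynthesis and anthocyanin genes leaned lower in tetraploid Col-0. Of 14 lignin synthesis genes, 7 fell and 1 rose, with 9 called when adjusted over the list alone (cameraPR adjusted p = 0.007), and COMT1 fell by 0.73 ± 0.09 in the authors' deposited table. Of 21 photosynthesis genes, 6 fell and 2 rose, with 9 called when adjusted over the list alone (adjusted p = 0.0098, and 0.077 at a correlation of 0.05). Near-identical copies moved apart in the authors' deposited table: LHCB1.1 gave −0.55 ± 0.06 against 0.46 ± 0.06 for LHCB1.2, and LHCB2.1 −0.83 ± 0.06 against 0.34 ± 0.07 for LHCB2.2, and how the authors' counting divided reads between copies was not measured here. Of 16 flavonoid and anthocyanin genes, 6 fell and 2 rose, with 9 called when adjusted over the list alone. The activator PAP1 fell by 0.91 ± 0.17 and the glycosyltransferase gene UGT79B1 by 1.39 ± 0.33 in the authors' deposited table, and the list's adjusted p of 0.04 became 0.12 at a correlation of 0.05, 0.011 with ranks and 0.054 with the count filter. Of 9 reference genes often used to normalize expression, 4 fell, with 4 called when adjusted over the list alone, UBQ10 by 0.92 ± 0.06 and ACT8 by 0.54 ± 0.08 in the authors' deposited table. The reference list's adjusted p was 0.0051, and 0.23 with ranks.

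The remaining Col-0 lists missed the threshold. Of 8 cellulose synthase genes 3 rose (list adjusted p = 0.073, and 0.024 with ranks), of 13 DNA methylation genes 5 rose (0.082), of 17 cell cycle genes 2 rose (0.39), and of 17 clock genes 2 rose and 3 fell (0.88). When adjusted over the list alone, 3, 5, 2 and 5 of these were called, in that order. In the authors' deposited table CESA7 gave 0.97 ± 0.23, CMT3 0.56 ± 0.11, MCM2 0.46 ± 0.11 and the clock gene PRR7 −0.84 ± 0.13. PRR9 also fell there (−0.53 ± 0.12), while the clock genes LHY and CCA1 rose (each 0.29 ± 0.07). The list test looks for a shift shared by the members, so for the clock it cannot show or exclude a change of phase. An index of 4 clock genes is given under Other observations. Of 16 jasmonate genes 3 rose and 1 fell, with 4 called when adjusted over the list alone (list adjusted p = 0.88), and of 23 salicylic acid defence genes 1 fell, with 1 called when adjusted over the list alone (0.88). Some of these defence genes varied widely between the Col-0 libraries, such as PR1 (−0.52 ± 0.86, mean count 1910) in the authors' deposited table. Markers of other tissues or states were low or uncalled. Of 8 listed root markers and 7 listed senescence markers 0 were called by the authors' DESeq2 fit or when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Of 4 listed seed storage markers, the oleosin genes OLEO1 and OLEO2 were called higher in the authors' deposited table at mean counts of 5.63 and 8.26, with 0 and 1 implied diploid reads, and were the 2 called when adjusted over the list alone. Both calls ended under the empirical null (adjusted p of 0.15 and 0.21, against 0.017 to 0.031 without a filter or with recentring). List adjusted p were 0.88 for root, 0.88 for senescence and 0.33 for seed storage markers, and 0.38 for FLC-repressing pathways, 0.89 for FLC activators, 0.88 for Polycomb machinery, 0.88 for demethylases and 0.9 for genes silenced by Polycomb. The mean log2 fold change and the test differed in sign for FLC activators (mean −0.17) and jasmonate genes (mean −0.21), where the test pointed up.

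The changes in Col-0 with the highest statistics were in genes of glucosinolate breakdown. ESP, whose protein directs breakdown to nitriles, was 123-fold higher in the tetraploid in the authors' deposited table (6.94 ± 0.07, mean count 32535). ESM1, which counteracts ESP and was chosen after its values were seen, was 15.2-fold lower in the authors' deposited table (−3.93 ± 0.07, mean count 8032). The directions of ESP and ESM1 were themselves a ground for the sign reading, so only their sizes are separate results. Other large rises were AT5G53700, 114-fold in the authors' deposited table (6.84 ± 0.70), and AT3G24542, AT4G07965 and AT1G50980, which had no diploid reads and were at least 657-, 583- and 189-fold higher. AT1G24807 had 2 implied diploid reads in the authors' deposited table and a ratio between 75.3 and 2264. The 6 largest falls by fitted log2 fold change, among called genes with a mean count of at least 100, lacked tetraploid reads: from the authors' deposited table, AT1G66100 was at least 2453-fold lower, AT3G47250 1283-fold, PLC8 1068-fold, AT5G49440 916-fold, AT3G44430 713-fold and AT5G46510 470-fold. In all, 103 called genes had no reads in tetraploid Col-0 and 44 had none in diploid Col-0.

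**Figure D2:**
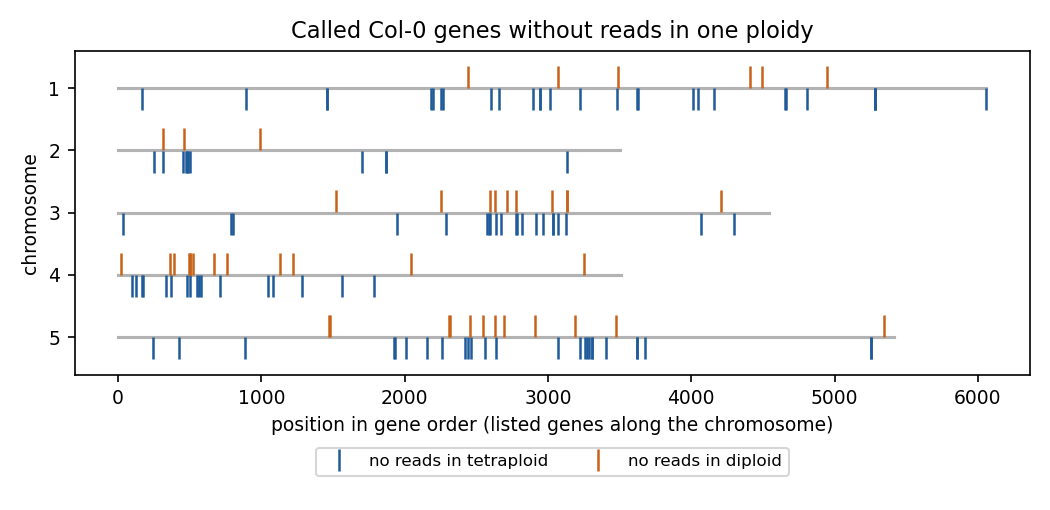
Position, by order of listed genes along each chromosome, of the called Col-0 genes without reads in one ploidy; blue ticks below a line are the 103 genes without tetraploid reads and orange ticks above it the 44 without diploid reads. Such genes lay on all 5 chromosomes, from 14 on chromosome 2 to 38 on chromosome 5.

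In Ler, 952 of 18683 genes with an adjusted p were called, 596 higher and 356 lower in the tetraploid, and 240 changed at least 2-fold, 214 of them higher. The split was near even with shrinkage and a local false sign rate, a cut not adjusted over genes, which gave 2225 genes, 1117 higher and 1108 lower. The other alternatives kept more rises than falls. The empirical null left 720, 461 higher and 259 lower. FLC gave 0.41 ± 0.29 (adjusted p = 0.56, mean count 111) in the authors' deposited table. The other named flowering and Polycomb genes were also uncalled. In the authors' deposited table MAF1 to MAF5 ranged from −0.24 ± 0.17 (MAF3) to 0.05 ± 0.75 (MAF5), SVP gave −0.09 ± 0.13, SOC1 0.19 ± 0.19, FT 0.26 ± 0.90 and CO −0.44 ± 0.34. CLF, SWN, EMF2 and LHP1 gave −0.21 ± 0.17, −0.30 ± 0.13, −0.18 ± 0.15 and 0.00 ± 0.17 in the authors' deposited table. Of 18 listed floral repressors, CDF3 (0.56 ± 0.11) and CDF1 (0.50 ± 0.11), repressors of CO, rose in the authors' deposited table, with 3 called when adjusted over the list alone (list adjusted p = 0.34). Of 19 floral promoters 0 were called by the authors' DESeq2 fit or when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.73). Median, mean and test did not share a sign for either list in Ler.

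Iron deficiency genes rose in tetraploid Ler as well, 11 of 15 members with 0 falling and 11 called when adjusted over the list alone (cameraPR adjusted p = 1.8e-27). In the authors' deposited table FRO3 gave 1.39 ± 0.16, IMA1 1.28 ± 0.17, IMA2 1.18 ± 0.16 and the iron transporter gene OPT3 0.67 ± 0.08. Salicylic acid defence genes rose, 10 of 23 with 0 falling and 14 called when adjusted over the list alone (adjusted p = 3.9e-24). The defence regulator ACD6 was 16.3-fold higher in the authors' deposited table (4.03 ± 0.29), the glucanase gene PR2 9.34-fold (3.22 ± 0.45), WRKY70 4.05-fold (2.02 ± 0.26) and PR5 2.92-fold (1.54 ± 0.21). Of 8 listed senescence markers 0 were called by the authors' DESeq2 fit and 2 had an unadjusted p under 0.05, with SAG13 at 3.05 ± 1.15 in the authors' deposited table and a list adjusted p of 0.09, or 0.023 with ranks.

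ABA and cold response genes rose in Ler, 11 of 20 with 0 falling and 13 called when adjusted over the list alone (adjusted p = 1.4e-12), among them RD29B (1.40 ± 0.30), RD26 (1.18 ± 0.25) and RD29A (0.93 ± 0.20) in the authors' deposited table. Of 16 flavonoid and anthocyanin genes 7 rose and 1 fell, with 10 called when adjusted over the list alone (adjusted p = 5.1e-10). DFR (0.73 ± 0.11), LDOX (0.72 ± 0.11) and PAP1 (0.84 ± 0.15) were among those higher in the authors' deposited table. Of 16 jasmonate genes 3 rose, with 5 called when adjusted over the list alone (adjusted p = 0.0013), AOC1 by 0.79 ± 0.18 in the authors' deposited table. Of 8 cellulose synthase genes 3 rose, with 4 called when adjusted over the list alone (adjusted p = 0.011, and 0.079 with ranks), CESA4 by 0.80 ± 0.20 in the authors' deposited table. Of 21 photosynthesis genes 2 fell and 1 rose, with 4 called when adjusted over the list alone, and LHCB6 fell by 0.26 ± 0.07 in the authors' deposited table. That list's adjusted p of 0.037 became 0.17 at a correlation of 0.05, 0.0089 with ranks and 0.071 with the count filter.

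Other Ler lists missed the threshold. Of 10 listed heat shock genes HSP101 (−0.75 ± 0.18) and HSP70 (−0.63 ± 0.19) fell in the authors' deposited table, with 3 called when adjusted over the list alone (list adjusted p = 0.12), and HSP70 lost its call under the empirical null (adjusted p = 0.058, against 0.033 and 0.042 without a filter or with recentring). Of 13 aliphatic glucosinolate genes CYP79F2 (0.86 ± 0.27) rose and of 9 indole ones CYP83B1 (0.43 ± 0.11) rose in the authors' deposited table, with 1 in each called when adjusted over the list alone (list adjusted p = 0.34 and 0.35). CYP79F2 lost its call under the empirical null (adjusted p = 0.074, against 0.042 and 0.035 without a filter or with recentring). Of 17 clock genes 1 rose and 2 fell (0.33), PRR9 by 0.56 ± 0.12 and LHY by −0.36 ± 0.08 in the authors' deposited table. Of 14 lignin genes 1 rose and 3 fell (list adjusted p = 0.34), and of 9 reference genes PP2AA3 rose by 0.40 ± 0.12 (0.095) in the authors' deposited table. When adjusted over the list alone, 4 clock, 4 lignin and 2 reference genes were called. In the remaining lists the authors' DESeq2 fit called 0 members, as did adjustment over the list alone, while an unadjusted p under 0.05 was listed for 3 DNA methylation genes, 2 FLC activators, 1 member each of the Polycomb machinery, demethylase, Polycomb-silenced, cell cycle and seed storage lists, and 0 of the others. List adjusted p were 0.34 for cell cycle, 0.12 for FLC-repressing pathways, 0.12 for FLC activators, 0.12 for Polycomb machinery, 0.33 for demethylases, 0.73 for genes silenced by Polycomb, 0.09 for DNA methylation, 0.61 for root and 0.29 for seed storage markers. With ranks, the lists of FLC-repressing pathways (adjusted p = 0.023), Polycomb machinery (0.032) and DNA methylation (0.032) passed the threshold, each lower in the tetraploid.

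Among the large rises in Ler in the authors' deposited table, AT1G08740, listed as a pseudogene in TAIR10.1, had no diploid reads and was at least 166-fold higher. AT1G35617 had 2 implied diploid reads and a ratio between 90.3 and 2712 in the authors' deposited table. AT2G34655 was 38.8-fold higher and PCR1, a cadmium resistance gene, 15.5-fold in the authors' deposited table, and AT1G13470 gave 4.17 ± 0.76 on the log2 scale. Falls were smaller. In the authors' deposited table NEET, an iron-sulphur protein gene, was 4.18-fold lower (−2.06 ± 0.16), AT3G16670 4.04-fold (−2.01 ± 0.27), the ferritin gene FER1 2.84-fold (−1.51 ± 0.14), AT2G46250 2.73-fold, AT3G55710 2.61-fold and AT5G38300 2.60-fold. Called genes without reads in one ploidy numbered 12 in Ler, all without diploid reads.

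**Figure D3:**
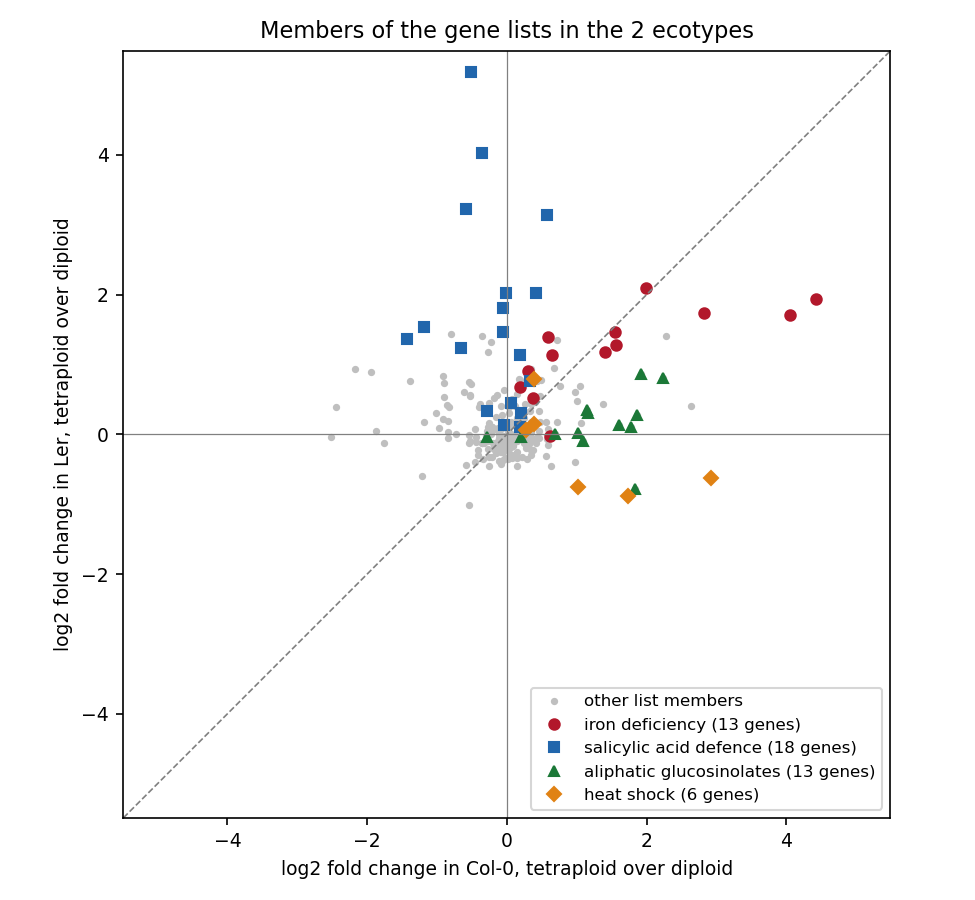
Log2 fold change, tetraploid over diploid, in Ler (vertical axis) against Col-0 (horizontal axis) for 272 members of the gene lists with a mean count of at least 10 in both tables; the dashed line marks equal change. Iron deficiency genes (red circles) lie to the upper right, salicylic acid defence genes (blue squares) rise along the Ler axis, and aliphatic glucosinolate genes (green triangles) and heat shock genes (orange diamonds) extend along the Col-0 axis.

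Whether the fold change between ploidies differed between the ecotypes was tested on the difference itself, which holds any difference between the lines as well as that of ploidy. Of 21361 shared genes, 1860 differed, 1061 with a higher fold change in Ler and 799 with a lower one, and 939 under the empirical null, 549 and 390. FLC differed by −2.21 ± 0.34 (Ler minus Col-0, Wald test on the authors' deposited table, adjusted p = 7.5e-09), SOC1 by 1.03 ± 0.32 (adjusted p = 0.022) and LHP1 by −0.69 ± 0.23 (adjusted p = 0.03). The empirical null of the difference kept FLC (adjusted p = 1.7e-05) and ended the calls of SOC1 (0.17) and LHP1 (0.19). SVP (0.44 ± 0.18, adjusted p = 0.1) and MAF5 (1.93 ± 0.97, adjusted p = 0.26), called in Col-0 alone, were not shown to differ by the same test on the authors' deposited table. Salicylic acid defence genes moved toward Ler, 10 of 23 with a higher and 0 with a lower fold change there, 10 also when adjusted over the list alone (cameraPR adjusted p = 1.1e-08). Flavonoid genes did so in 8 of 16, or 9 when adjusted over the list alone (adjusted p = 3.3e-06). Aliphatic glucosinolate genes differed the other way in 8 of 13, or 11 when adjusted over the list alone (cameraPR adjusted p = 4.8e-09). Heat shock genes also did so in 3 of 8, or 3 when adjusted over the list alone. Their cameraPR adjusted p was 2.3e-08, and 0.042 with ranks. DNA methylation genes had a lower fold change in Ler in 2 of 13, or 3 when adjusted over the list alone. That list's cameraPR adjusted p was 0.011, and 0.051 at a correlation of 0.05. Reference genes had a higher fold change in Ler in 2 of 9, or 4 when adjusted over the list alone (cameraPR adjusted p = 6e-04). Iron deficiency genes gave no list difference (cameraPR adjusted p = 0.98), with a higher fold change in Ler for 2 members and a lower one for 1. Genes of FLC-repressing pathways had a lower fold change in Ler with ranks (cameraPR adjusted p = 0.012) but not with statistics (0.11). Of the 2757 shared genes called in Col-0 and not in Ler, 1280 differed by this test, and of the 581 called in Ler and not in Col-0, 252 did.

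Overlap between the ecotypes was above the number expected from independent calls in both shared directions. Over 18240 genes, 115 rose in both against 42.5 expected (Fisher's exact odds ratio 3.34, p = 2.1e-23) and 98 fell in both against 30.3 expected (odds ratio 4.31, p = 1.5e-26). Opposite calls were also above chance, with 49 genes higher in Col-0 and lower in Ler against 26.6 expected, and 70 the other way against 48.5 expected. Across 13324 genes with a mean count of at least 100 in both tables, which are not independent replicates, the log2 fold changes had a Spearman rho of 0.076 and a Pearson r of 0.105. The leading shared rises in the authors' deposited table were AT1G13470 (3.28 ± 0.30 in Col-0, 4.17 ± 0.76 in Ler), BHLH38 (4.42 ± 0.84 and 1.94 ± 0.40), BHLH100 (2.82 ± 1.04 and 1.74 ± 0.40), BHLH39 (4.05 ± 1.18 and 1.71 ± 0.49) and PUB19 (1.62 ± 0.31 and 2.68 ± 0.17). The Col-0 calls of BHLH39 and BHLH100 ended under the empirical null, with adjusted p of 0.089 and 0.27, against 0.0062 to 0.048 without a filter or with recentring. The leading shared falls in the authors' deposited table were FER1 (−1.32 ± 0.09 and −1.51 ± 0.14), AT1G13650 (−2.83 ± 0.23 and −1.18 ± 0.13), AT3G55710 (−2.12 ± 0.27 and −1.38 ± 0.24), AT3G16670 (−1.08 ± 0.09 and −2.01 ± 0.27) and BBX14 (−1.31 ± 0.09 and −1.04 ± 0.16).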

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

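The tests of the explanations for FLC and for genes without reads were chosen after the results were seen, apart from that on chromosome medians. The fold change between ploidies differed between ecotypes by a Wald test in 1860 genes, and in 939 under the empirical null. Each line goes with its ploidy in this design, so these differences are not by themselves effects of ploidy. By cameraPR on the same statistics, the mean Wald statistic of the difference, Ler minus Col-0, was 2.79 for salicylic acid defence genes, 2.66 for flavonoid genes, 2.63 for reference genes, −4.08 for heat shock genes, −3.49 for aliphatic glucosinolate genes and −1.6 for DNA methylation genes.

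Among single genes, the same test on the authors' deposited table gave log2 differences, Ler minus Col-0, of 13.39 for AT3G47250, 12.83 for PLC8, 11.83 for AT3G43740, 11.27 for AT1G23960 and 10.74 for AT1G25097. It gave −10.37 for AT4G04402, −9.33 for AT5G17100, −9.32 for AT1G27570, −7.03 for AT5G53700 and −6.38 for AT2G01021. Apart from AT1G25097, AT5G53700 and AT2G01021, these are fitted values of genes without reads in one ploidy of Col-0 and are no measure of size. SOC1 differed by 1.03 and LHP1 by −0.69. The empirical null ended the calls of SOC1 (adjusted p = 0.17), LHP1 (0.19) and AT3G43740 (0.065).

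FLC differed by −2.21 between the ecotypes (95% bounds −2.88 and −1.55), which argues against a ploidy effect on FLC that is alike in both as the whole cause. A genetic difference close to FLC in the tetraploid Col-0 line stays open. Among the 50 listed genes on each side of FLC, 1 lacked reads in one ploidy, a number that 65% of such windows stayed below, and no value here could exclude a single nearby variant. The line and its ploidy go together in this design, so they cannot be told apart for FLC. An effect of ploidy particular to Col-0, which the design names, also stays open and untested.

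The 147 called genes without reads in one ploidy of Col-0 lay on all 5 chromosomes but were clustered in gene order. Of 231 bins of 100 listed genes, 76 held at least 1, against a median of 108 and bounds of 100 and 116 in sets matched on mean count, and a bin held at most 8. What the clustering reflects was not tested. Gain or loss of whole chromosomes is argued against by chromosome medians of at most 0.031 in size on the log2 scale. A ploidy effect alike in both ecotypes is argued against by the 49 of these genes that Ler expressed, whose median log2 fold change in Ler, signed by the direction in Col-0, was −0.03 (bounds −0.12 and 0.16). Ler material in the tetraploid Col-0 libraries was not settled. Of the genes without tetraploid reads, 44.7% were listed in Ler at 10% or more of their diploid Col-0 level (46 of 103, exact binomial bounds 34.9% and 54.8%). That goes against it, but the Ler table rests on another annotation, so reads counted there may be missed in the Col-0 table. Single genes went both ways. ESP and ESM1 in tetraploid Col-0 had levels nearer diploid Ler than diploid Col-0, while MAM1, low in Ler, rose (values under Other observations). The sign reading itself rests on ESP and ESM1, so these genes cannot tell which ploidy of Col-0 is nearer Ler. Also open is a hypothesis that the diploid and tetraploid Col-0 lines may differ genetically at many loci. Of the 147 genes, 49% were unlisted or under 10% of their Col-0 level in the separately normalized Ler table. Matched sets gave a median of 6.8% and an upper bound of 11.6%. Part of this may come from the other annotation of the Ler table, and the sets were matched on mean count only. An effect of ploidy particular to Col-0 at these genes stays open too and was not tested.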

How the results depend on the processing

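The alternatives without genes that lack reads, or have under 1 implied read, in one ploidy, and those matching Ler identifiers by locus code, were chosen after seeing the data. Of 38 alternatives for the counts of genes and lists, 26 stayed within 1.5 times the main value. Requiring an absolute log2 fold change of at least 1 left 1094 genes in Col-0 and 240 in Ler, a difference of at least 1 left 854 genes, and the fold minimum in both left 32 shared genes. An adjusted p under 0.01 left 548 genes in Ler, 1220 differences and 120 shared genes. The empirical null left 1799 genes in Col-0 and 939 differences, since the Wald statistics had 1.31 and 1.25 times the spread of the theoretical null there, against 1.05 in Ler. Shrinkage with a local false sign rate gave 5126 genes in Col-0 and 2225 in Ler. That rate was cut at 0.05 for each gene without adjustment over genes, and 5183 and 3001 genes had an unadjusted p under 0.05. A correlation of 0.05 left 5 lists in Col-0 in place of 9, which its wider null produces. Among 309 results for named genes, 30 lost their call under the empirical null, 2 without a filter and 3 with recentring, which also added 1 call. The 309 include uncalled results, which had no call to lose, so the share lost among called ones is larger. Of 74 called differences of named genes, 24 lost their call under the empirical null. No called named gene and no called list turned its direction under these alternatives. For genes this was nearly fixed in advance, since the alternatives run on single genes keep the sign or move the estimate little. No paired analysis was possible because the tables hold no values per numbered library. For the same reason DESeq2 against TMM scaling, a replicate block, leaving out replicates and an estimated inter-gene correlation were not run, and the alternative without a count filter adjusted the deposited p over all genes. With 2 libraries per group and no values per library, an outlying library cannot be identified, and low genes such as FT cannot show a change of moderate size. Standard errors still showed spread between libraries for some well-counted Col-0 genes, against the median of 0.15. They were 0.86 for PR1, 1.36 for FMO1, 1.22 for PAD3, 0.84 for BHLH38, 1.18 for BHLH39 and 1.04 for BHLH100. Fold changes of such defence and iron genes in Col-0 are therefore uncertain.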

Other observations

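The tests of the clock and of ferritin were chosen after results were seen, for ferritin those of FER1 and FER4 in Ler. The genes of this paragraph were chosen after their values were seen. In the authors' deposited table the defence-related gene ECS1 gave −1.90 ± 0.17 in Col-0 and 3.72 ± 0.26 in Ler, a difference of 5.63 ± 0.31. AT4G14390, a neighbour of ACD6 in the gene order of TAIR10.1, gave 5.18 ± 0.51 in Col-0 in the authors' deposited table. In Ler it had no diploid reads, a mean count of 3.82 and no adjusted p in the authors' deposited table, and was at least 5.17-fold higher. MAM1, a gene of glucosinolate chain elongation, had mean counts of 6317 in Col-0 and 17.2 in Ler in the authors' deposited tables, which were normalized separately. It rose by 1.84 ± 0.17 in tetraploid Col-0 in the authors' deposited table. ESP and ESM1 had implied counts of 64546 and 992 in tetraploid Col-0 and of 32266 and 855 in diploid Ler, against 524 and 15073 in diploid Col-0, from the authors' deposited tables, which were normalized separately.

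Iron deficiency genes were higher in tetraploids of both ecotypes. Harvest at another clock phase, alike in both ecotypes, is argued against by 4 clock genes. The morning index, the mean log2 fold change of CCA1 and LHY minus that of PRR7 and PRR9, was 0.97 ± 0.10 in Col-0 and −0.45 ± 0.11 in Ler, opposite in sign. In Ler the sign rests on LHY and PRR9, since CCA1 (−0.03 ± 0.09) and PRR7 (−0.06 ± 0.14) were uncalled, so the argument is limited. A harvest phase that differed between ploidies in another way, such as in Col-0 alone, stays open and was not tested. A lower iron supply signal in tetraploids of both ecotypes stays open as a hypothesis. The ferritin genes FER1, FER3 and FER4, which iron induces, had a median log2 fold change of −0.74 in Col-0 and −1.18 in Ler, with 2 and 3 of the 3 called lower, which is consistent with it. Soil, watering or sampling may differ between the plants in ways the labels do not give, and these were not tested.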
